A study of Mus musculus with 4 samples.

How the data were processed

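Methylated RNA immunoprecipitation sequencing (MeRIP-seq) was used to map N6-methyladenosine (m6A) in mouse liver RNA. In this assay RNA is fragmented, fragments carrying m6A are pulled down with an antibody, and the immunoprecipitated (IP) fragments are sequenced beside the untreated input, so that a peak is a stretch of transcript with more IP reads than the input accounts for. The series held 4 libraries, an IP and an input from livers of mice with a floxed Alkbh5 gene (FF) and an IP and an input from livers of Alkbh5 knockout mice (HKO, an abbreviation that the labels do not spell out). ALKBH5 is an enzyme that removes m6A from RNA. Per the labels, the mice were 9 weeks old and ate normal chow, and 300 μg of RNA from 3 mice was pooled for each genotype. Fragments of about 100 nt were incubated with the antibody for 2 h, and libraries were sequenced as paired reads of 150 bp. Samples were grouped by their titles. There was 1 pool and 1 IP library per genotype, and therefore no replicate.

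The sources disagree on reagents: the series design text names an antibody from Synaptic Systems and a New England Biolabs library kit, while the sample protocols name an antibody from Millipore and a NuGEN kit. The choice between them was not settled here. It bears on which strand and which parts of a transcript the reads cover.

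The authors called peaks separately for each genotype, IP against its own input, with exomePeak 2.16.0 at a q-value threshold of 0.05, per the series design text. The submitters' processing notes name fastp 0.19.11, BWA 0.7.12, HOMER 4.9.1 and genome build GRCm38.p6. The 2 deposited peak lists give a position, strand, exon blocks and gene symbol for every peak. The score column of the deposited lists was read as a p-value of each peak, since its logarithm matched the separately listed log10 p-value to within rounding. The authors' q-value per peak is listed as its log10, a score with no lower bound, and peaks whose q fell below the smallest number the files could hold are listed at minus infinity. The fold enrichment per peak is the authors' ratio of IP over input. These values per peak are the authors' own and were used only to describe, rank or filter peaks within a list.

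Peak lists hold no read totals, so the depth of each library is unknown, and a longer list can come from deeper sequencing or a better enrichment. Absence of a peak from a list does not show that the RNA was unmethylated, since a transcript with few reads gives no peak. Fold values set side by side for both genotypes come from separate IP reactions and give no direction of change. Confidence intervals are 95% Wilson intervals and cover counting error only. No p-value is given between genotypes.

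The lists were compared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Peaks of the 2 lists were called shared if their exon blocks overlapped by at least 1 bp on the same strand, and list-specific otherwise. A list-specific peak was called strong at a q of 1e-05 or less and a fold enrichment of 2 or more. A gene was assigned to a single list if it had a peak in that list and none in the other. Coordinates are on GRCm38.p6 and are given from base 1. The gene symbols of 3 peaks in each list did not match the RefSeq gene table, and those peaks have no position along a gene. The overlap step was tested on simulated data made from the FF list of 14057 peaks. There, 9737 of 9737 peaks shifted by a short distance were found as shared, and the others had been moved to an empty sequence. This outcome was built into the simulation and checks the code only.

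Position in untranslated and coding regions, and the share of peaks with the m6A sequence motif, had been planned and were not analysed here, because they need transcript models and a genome sequence and only gene spans were used. In their place, after the lists were seen, the centre of each peak's exonic sequence was placed within 500 bp of the annotated gene start, within 1000 bp of the annotated gene end, or in the last 10% of the gene span. An annotated start is that of the whole gene span, so a promoter inside the gene is not counted.

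Gene lists were fixed before the data were examined. They covered m6A writers, m6A erasers, m6A readers, glucagon signalling and gluconeogenesis, insulin signalling, EGF receptor and mTORC1 signalling, lipogenesis and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and ketogenesis, lipoprotein and lipid transport, bile acid synthesis and transport, and xenobiotic metabolism. Further lists covered the circadian clock, secreted hepatocyte proteins, amino acid and urea metabolism, acute phase and cytokine signalling, stress and immediate early genes, autophagy and lysosome, Wnt and zonation, hepatocyte transcription factors, and markers of Kupffer cells and macrophages, liver endothelial cells, hepatic stellate cells and fibroblasts, cholangiocytes, and lymphocytes and other leukocytes. For each list the balance was the number of genes with a peak in the HKO list alone minus the number in the FF list alone, divided by the members with a peak in either list. Its percentile was taken among 10000 random gene sets of the same size, drawn from genes with a peak in either list and matched on the larger number of peaks per gene (1, 2, or 3 and more). This describes these libraries and is not a test between genotypes. Genes in opposite single lists cancel in the balance, so a middle percentile does not show that members had peaks in both lists. In a check on the genes of the deposited lists, a planted set of 10 genes from the HKO list alone and 10 genes in both lists reached percentile 100. Of 200 random sets of genes, 97.0% fell inside the middle 95% (9650 genes).

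Named genes follow a rule fixed before the data were examined. It takes Alkbh5 and every m6A writer, eraser and reader; Gcgr, Egfr and up to 4 members per fixed list and direction with a peak in a single list, by smallest q; the 10 genes per genotype with strong list-specific peaks of smallest q; the 5 genes per list with the most list-specific peaks, ties by symbol; and the 5 shared peaks with the largest smaller fold of the 2 lists. Ties in q were ordered by larger fold. Alternatives changed the q threshold, the fold filter, the overlap, the length of the lists and the unit counted, and further ones on peak position were added after the data were seen.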

Results

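The data comprised 2 lists of m6A peaks in mouse liver RNA, 1 from FF livers and 1 from HKO livers, each called from an IP library against its input and each made from RNA of 3 pooled mice. The FF list held 14057 peaks on 8376 genes and the HKO list 14693 peaks on 8565 genes. Peaks had a median exonic length of 241 bp in the FF list and 269 bp in the HKO list, and covered 4436 kb and 4788 kb of exon. The median fold enrichment over input was 8.80 in the FF list (interquartile range 4.47 to 14.9) and 10.4 in the HKO list (5.02 to 17.8). Protein-coding genes carried 94.7% of FF peaks and 94.8% of HKO peaks, and long non-coding RNA genes 4.80% and 4.72%. At a q of 1e-05 or less, 8764 FF peaks and 9621 HKO peaks were left. With 1 pool per genotype, no difference between the lists has a replicate check.

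The study set out to map how loss of ALKBH5 alters m6A in liver RNA, and the knocked-out gene was examined first. Alkbh5, on the plus strand of chromosome 11 (GRCm38.p6), had 3 peaks in the FF list and 0 in the HKO list. Of the 3 FF peaks, those at 60537713 to 60537893 (fold 18.8, log10 q -4.05) and at 60537983 to 60538702 (fold 5.22, log10 q -10.1) were centred 120 bp and 660 bp from the gene start. The peak at 60554256 to 60554526 had a fold of 8.05 and a log10 q of -17.0, and its centre lay 4121 bp from the gene end. The peak lists do not give the RNA level of Alkbh5, and the part of the gene deleted in these mice is not given in the sources used here. Fto, the other known m6A demethylase, had 1 peak in the HKO list at 91409309 to 91409816 on chromosome 8 (fold 5.94, log10 q -13.3) and 0 in the FF list.

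**Figure D1:**
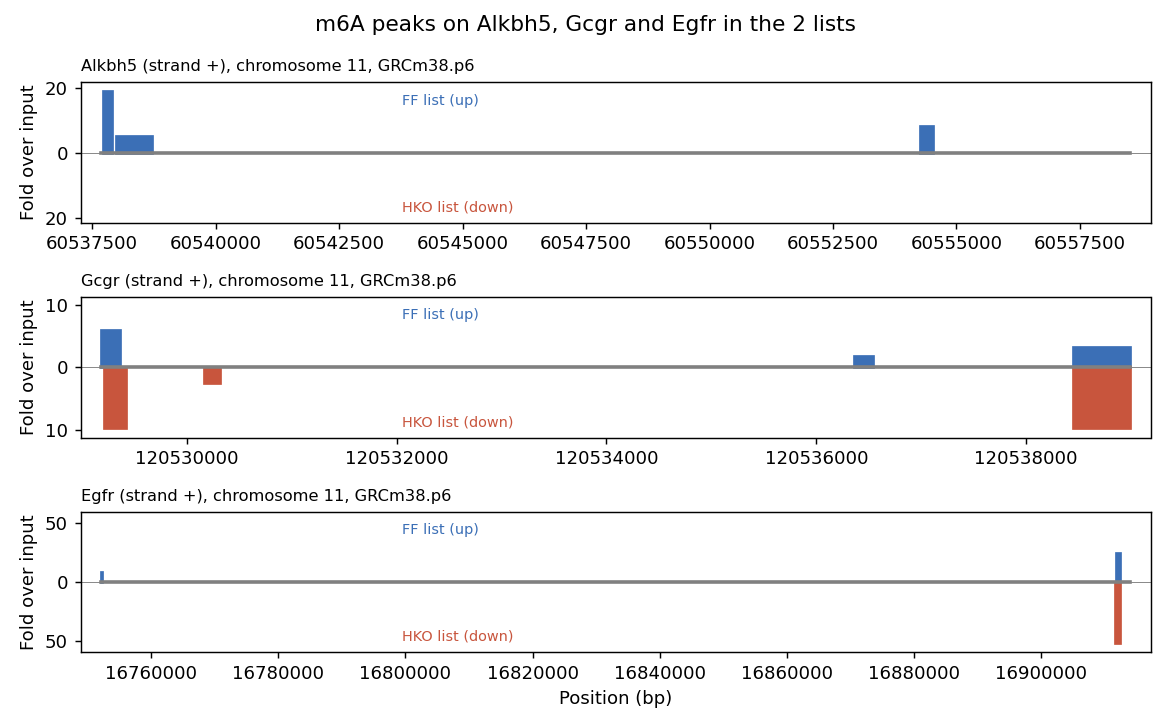
Peaks on Alkbh5, Gcgr and Egfr by position on chromosome 11 (bp, GRCm38.p6), with the authors' fold enrichment over input as bar height, FF peaks upward and HKO peaks downward, and the gene span as a grey line. Alkbh5 has 3 FF peaks and 0 HKO peaks, whereas the peaks near the ends of Gcgr and Egfr are in both lists.

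Most of the genes that write or read m6A had peaks in both lists. Of 11 writer genes, 10 had a peak and 8 had peaks in both lists, including Wtap with 3 and 3 (FF and HKO), Virma with 3 and 4, Zc3h13 with 4 and 4, Rbm15 with 8 and 4, Rbm15b with 4 and 3, Cbll1 with 1 and 2, and Mettl16 and Zcchc4 with 1 and 1. Mettl3, which encodes the catalytic subunit of the main m6A methyltransferase, had no peak in either list. Mettl14, its partner subunit, had 1 peak in the HKO list (fold 3.39, log10 q -1.83) and none in the FF list, and Mettl5, a methyltransferase of ribosomal RNA, had 1 peak in the FF list (fold 4.18, log10 q -4.26) and none in the HKO list. Of 14 reader genes, 10 had a peak, each of them in both lists, with 6 and 4 on Ythdc1, 3 and 2 on Ythdf3, 2 and 2 on Ythdf2 and on Hnrnpa2b1, 2 and 1 on Elavl1, 1 and 2 on Fmr1, and 1 and 1 on Ythdf1, Ythdc2, Hnrnpc and Rbmx. Igf2bp1, Igf2bp2, Igf2bp3 and Prrc2a had none. The reader genes carried 3 FF-specific and 2 HKO-specific peaks. Among them were the Hnrnpc peaks, which did not overlap each other, and an FF peak on Ythdc1 (fold 52.5, log10 q -17.5). The balance between the lists stood at percentile 45.3 of random gene sets for writers, 48.9 for erasers and 45.5 for readers. For the erasers this middle value does not mean that peaks were kept. Neither eraser had peaks in both lists, and Alkbh5 and Fto, in opposite lists, cancelled to a balance of 0. Counting peaks in place of genes put the 2 erasers at percentile 1.64, while the other settings left them between 45.2 and 48.9. The value of 1.64 rests on the 3 FF peaks of Alkbh5 against 1 HKO peak of Fto.

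The m6A landscape was largely shared. Of the FF peaks, 10518 (74.8%, 74.1 to 75.5) overlapped an HKO peak, and of the HKO peaks, 10511 (71.5%, 70.8 to 72.3) overlapped an FF peak. The highest fold values present in both lists belonged to Zkscan6 (156 in FF and 148 in HKO), Hivep2 (143 and 131), Sema6d (117 and 132), Zbtb2 (97.1 and 102) and Kbtbd2 (83.8 and 103). Shared peaks had a median log10 q of -12.5 in the FF list and -14.7 in the HKO list, and list-specific peaks -3.17 and -3.57. List-specific peaks were also shorter, with a median of 151 bp in both lists against 300.0 bp and 329 bp for shared peaks. Peaks were present on 9650 genes in either list and on 7291 (75.6%) in both. A further 1085 genes had a peak in the FF list and none in the HKO list, and 1274 the reverse (54.0% of the 2359 genes, 52.0 to 56.0). With both lists taken to the length of the shorter, these became 1172 and 1141, so the larger HKO number turned, while at a q of 1e-05 or less in both lists they were 706 and 1154.

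Gcgr, the glucagon receptor gene, carried peaks near both ends of the gene in both lists. The peak at 120538445 to 120538989 on chromosome 11, centred 269 bp from the gene end, had the same limits in each list and a fold of 3.20 in FF and 9.72 in HKO. Near the start, the peaks at 120529185 to 120529364 (FF, fold 6.01) and 120529215 to 120529424 (HKO, fold 9.76) overlapped. Gcgr also had a list-specific peak in each list, at 120536360 to 120536540 in FF (fold 1.81, log10 q -13.1) and at 120530168 to 120530317 in HKO (fold 2.57, log10 q -5.61). Among 23 glucagon signalling and gluconeogenesis genes with a peak, 21 had peaks in both lists. Slc37a4, the glucose-6-phosphate transporter (fold 3.77, log10 q -15.9), and Prkar1a, a regulatory subunit of protein kinase A (fold 2.46, log10 q -8.43), had a peak in the HKO list and none in the FF list. The list stood at percentile 83.4 of random gene sets.

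Egfr, the epidermal growth factor receptor gene, carried a shared peak about 2 kb before the gene end, at 16911662 to 16912380 on chromosome 11 in FF (fold 24.7) and at 16911542 to 16912350 in HKO (fold 51.7). A second FF peak, at 16752203 to 16752353 (fold 8.62, log10 q -6.13), was centred 75 bp from the gene start and overlapped no HKO peak. Of 28 EGF receptor and mTORC1 signalling genes with a peak, 24 had peaks in both lists. Rheb, the GTPase that activates mTORC1, had a peak centred 75 bp from its start in the FF list (fold 3.73, log10 q -11.7) and none in the HKO list. Fnip1, Tsc2 and Mtor had a peak in the HKO list and none in the FF list, with log10 q of -10.3, -6.81 and -2.40. Of 19 insulin signalling genes, 16 had peaks in both lists; Akt1 had 2 FF peaks and 0 HKO peaks, while Grb14, an inhibitor of the insulin receptor (fold 33.3, log10 q -34.2), and Gys2, the liver glycogen synthase (fold 6.45, log10 q -4.87), had an HKO peak and no FF peak. These lists stood at percentiles 73.9 and 68.1.

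Genes of cholesterol and bile acid metabolism had more members in the HKO list alone than in the FF list alone. Of 22 cholesterol synthesis and uptake genes with a peak, 5 were in the HKO list alone, among them Nsdhl (log10 q -38.0), Scap (-17.8), Mvk (-4.76) and Mvd (-3.77), and 1 was in the FF list alone, Srebf2, with peaks centred 105 bp from the start and 1240 bp from the end of the gene. Of 20 bile acid genes, 4 were in the HKO list alone and 0 in the FF list alone. The 4 were Cyp27a1, an enzyme of the alternative pathway of bile acid synthesis, Abcb4, the canalicular phospholipid transporter, Fgfr4, the receptor for the ileal hormone that represses bile acid synthesis, and Akr1d1, a steroid reductase. Their folds were 5.79, 4.78, 3.56 and 4.24, and the first 3 were centred 149 bp, 105 bp and 240 bp from the gene end. The balances stood at percentiles 96.4 and 96.3, inside the middle 95% of random gene sets. With a fold of 2 or more required in both lists they stood at 98.3 and 98.5, outside that range, but at a q of 1e-05 or less in both lists the cholesterol genes stood at 50.4, with no lean left, and the bile acid genes at 95.5.

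Xenobiotic and amino acid metabolism also had more genes in the HKO list alone than in the FF list alone. Of 22 xenobiotic genes with a peak, Cyp2e1 (fold 12.5), Cyp2c29 (1.84), Nqo1 (28.4) and Gsta3 (3.87) had an HKO peak and no FF peak, and none had the reverse (percentile 93.2). The percentile was 97.5 at a q of 1e-05 or less in both lists, 85.4 at a fold of 2 or more, and 46.1 with peaks counted in place of genes, where no lean was left. Each of the 4 peaks was centred within 270 bp of the gene end. Of 25 amino acid and urea metabolism genes, Hpd, Tdo2, Ass1 and Cps1, the latter pair being enzymes of the urea cycle, had an HKO peak and no FF peak, with folds of 2.91, 3.33, 1.93 and 2.79. Sds and Mat1a had an FF peak and no HKO peak, with folds of 1.75 and 4.07 (percentile 71.9). Counting peaks gave 97.7, and the settings of q and fold gave 60.9 to 81.3. Reads of Cyp2c29 may be shared with other members of its subfamily, so its peak is uncertain.

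Most lipid genes had peaks in both lists, namely 17 of 23 lipogenesis and triglyceride synthesis genes with a peak, 14 of 18 lipoprotein and lipid transport genes, and 16 of 18 fatty acid oxidation and ketogenesis genes. In the first list Dgat1 (fold 10.8), Plin2 (1.31) and Gpam (3.26) had an FF peak and no HKO peak, and Fads1 (1.66), Nr1h2 (2.98) and Srebf1 (2.69) the reverse (percentile 42.6). In the second Apoa2 (2.63) and Apoc3 (4.41) were in the FF list alone, and Lcat (5.64) and Mttp (2.38) in the HKO list alone (percentile 43.8). Fatty acid oxidation and ketogenesis had Fgf21 (4.05) in the FF list alone and Cyp4a14 (2.92) in the HKO list alone (percentile 43.7). Reads of Cyp4a14 may be shared with other members of its subfamily, so its peak is uncertain. Of 20 genes for secreted hepatocyte proteins, Alb (1.57) and Igfbp2 (2.27 at its peak of smallest q) were in the FF list alone, and Ttr (1.61), Igf1 (2.76 at its peak of smallest q) and Hgfac (3.21) in the HKO list alone (percentile 64.0).

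Several programmes of liver gene control had no member in a single list. All 17 circadian clock genes, all 21 Wnt and zonation genes and all 19 hepatocyte transcription factor genes with a peak had peaks in both lists (percentiles 44.6, 43.6 and 44.2). Of 21 acute phase and cytokine signalling genes, Stat3 and Saa1, a member of a family of close copies and hence uncertain, were in the FF list alone and Irf1 in the HKO list alone (percentile 26.8). Stress and immediate early genes had Mt1 in the FF list alone and Klf6 in the HKO list alone among 22 (percentile 43.3), and autophagy and lysosome genes had Atg3 and Lamp2 among 21 (percentile 43.0).

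Markers of other liver cell types lay within the middle 95% of random gene sets. All 11 endothelial markers with a peak had peaks in both lists (percentile 45.1). Among 11 Kupffer cell and macrophage markers, Lyz2 was in the FF list alone and Mrc1 in the HKO list alone (percentile 45.2). Among 10 stellate cell and fibroblast markers, Ecm1 was in the FF list alone and Col1a1 and Dcn in the HKO list alone (percentile 68.6). Cholangiocyte markers had Muc1 in the FF list alone and Spp1 in the HKO list alone among 4 (percentile 47.1), and leukocyte markers had Itgax and S100a9 among 3 (percentile 47.3). With so few members the random balances spread widely, from -0.5 to 0.5 for cholangiocyte and from -0.667 to 0.667 for leukocyte markers. Only a near-complete lean would fall outside, so their place inside says little. Across the 25 lists, 342 of 408 genes with a peak had peaks in both lists, and 0 lists fell outside the middle 95% of random gene sets.

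**Figure D2:**
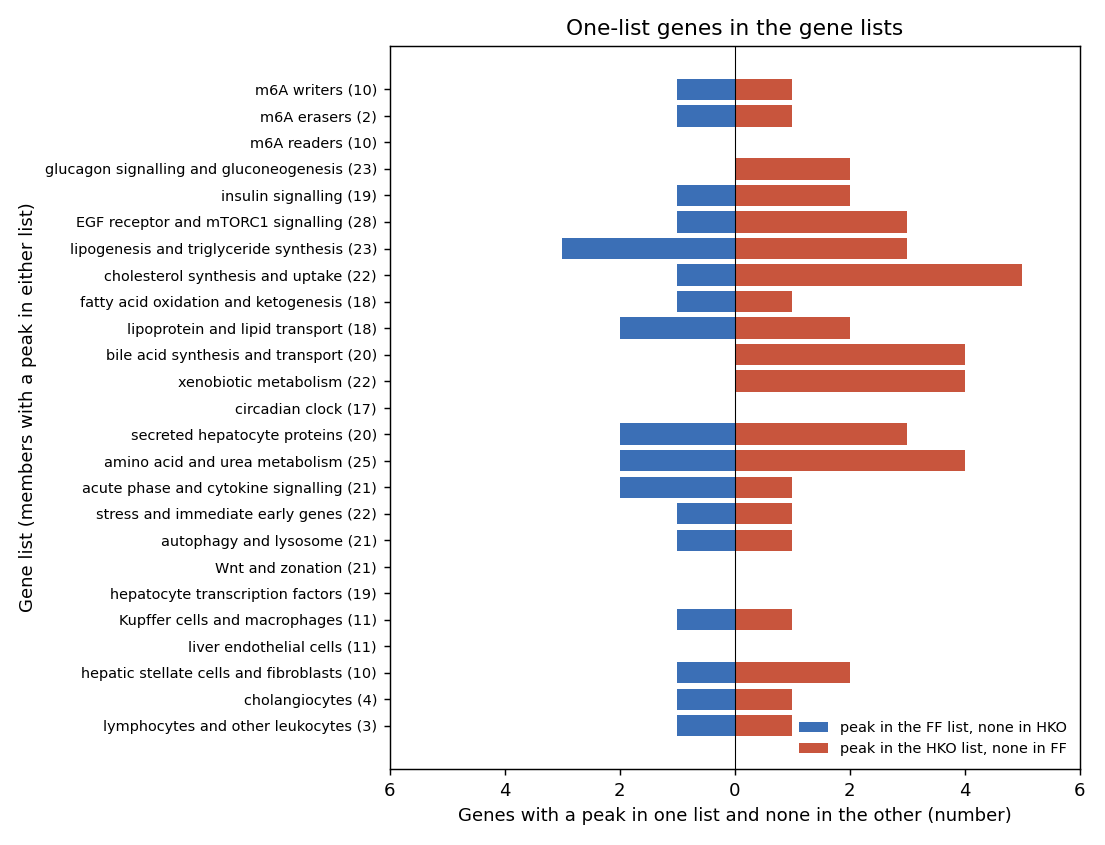
Number of genes in each fixed gene list with a peak in the FF list alone (left of 0) or in the HKO list alone (right of 0). Cholesterol synthesis and uptake has 5 genes on the HKO side and 1 on the FF side, and bile acid synthesis and transport has 4 and 0.

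Strong list-specific peaks numbered 899 in the FF list and 1304 in the HKO list. In the FF list those of smallest q lay on Apoa2, an apolipoprotein of high-density lipoprotein, Mpc2, a subunit of the mitochondrial pyruvate carrier (fold 7.48, log10 q -206), and Sephs2, which makes the selenium donor for selenoproteins (4.80, -180). They were followed by Gch1 (4.22), Agxt (4.27), Hsp90ab1 (2.24), Serpinc1 (3.10), Lrg1 (3.30), Nop53 (15.3) and Ndufb7 (3.90). The peaks on Mpc2, Sephs2, Gch1, Agxt, Nop53 and Ndufb7 were centred 105, 269, 164, 150, 135 and 118 bp from the gene start. In the HKO list those of smallest q, all listed at minus infinity on the log10 scale, lay on Serpina1d (fold 182), Serping1 (17.3), Cyp2e1 (12.5), Mup11 (8.01), Cyp27a1 (5.79), Serpina1e (5.22), Cyp3a25 (4.80), Serpina1a (3.53), Serpina1b (3.15) and Hpd (2.91). The peaks on Serping1, Cyp2e1, Mup11, Cyp27a1, Serpina1b and Hpd were centred 119, 194, 161, 149, 60 and 119 bp from the gene end. Serpina1a, Serpina1b, Serpina1d, Serpina1e, Mup11 and Cyp3a25 belong to families of related genes that may share reads, and their peaks are uncertain. Requiring no peak of the other list anywhere in the gene left 329 FF and 478 HKO peaks, a q of 1e-03 gave 1800 and 2490, and a q of 1e-10 gave 362 and 583.

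Some genes carried several list-specific peaks. Spen, a transcriptional repressor, had 7 HKO peaks that overlapped no FF peak, Srrm2, a component of nuclear speckles, had 6, and F5 (coagulation factor V), Golgb1 and Helz2 had 5 each. In the FF list Cgn, Crtc3, Klf15, Mib2 and Prox1 had 4 each. Of these 10 genes, all but Mib2 also had peaks that overlapped between the lists.

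List-specific peaks of the lists differed in their position along the gene. Of the FF-specific peaks, 1227 of 3537 (34.7%, 33.1 to 36.3) were centred within 500 bp of the annotated gene start, against 197 of 4180 HKO-specific peaks (4.71%, 4.11 to 5.40). Shared peaks stood at 8.39% in the FF list and 8.44% in the HKO list, values that lie close because shared peaks overlap each other by definition. Towards the gene end the order was the opposite, with 33.6% (32.2 to 35.0) of HKO-specific peaks and 17.1% (15.8 to 18.3) of FF-specific peaks centred within 1000 bp, and 29.7% and 29.9% of shared peaks. Among strong list-specific peaks the start share was 49.6% (46.3 to 52.8) in FF and 2.69% (1.94 to 3.71) in HKO, and the end share 12.7% (10.7 to 15.0) and 43.1% (40.4 to 45.8). Within the HKO list, peaks at gene starts had a median fold of 5.86 (interquartile range 3.30 to 11) against 11 (5.26 to 18.7) elsewhere. The lower value came from shared peaks (5.35 against 11.9), since HKO-specific peaks had 9.33 at starts and 8.91 elsewhere. Within the FF list the medians were 8.81 (4.60 to 13.9) and 8.80 (4.44 to 15.0).

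Of the 23 fixed genes in the FF list alone, 13 had a peak centred within 500 bp of the gene start, including Rheb, Srebf2, Alb, Apoc3, Fgf21, Mat1a, Dgat1, Stat3 and Lyz2, and 3 had one within 1000 bp of the gene end. Of the 43 fixed genes in the HKO list alone, 5 had a peak at the start and 23 one at the end, including Cyp2e1, Cyp27a1, Abcb4, Fgfr4, Hpd, Ass1, Lcat and Mttp. With a window of 200 bp the shares at starts were 24.1% of FF-specific and 2.75% of HKO-specific peaks, and among list-specific peaks with a q of 1e-10 or less they were 56.5% and 1.91%.

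**Figure D3:**
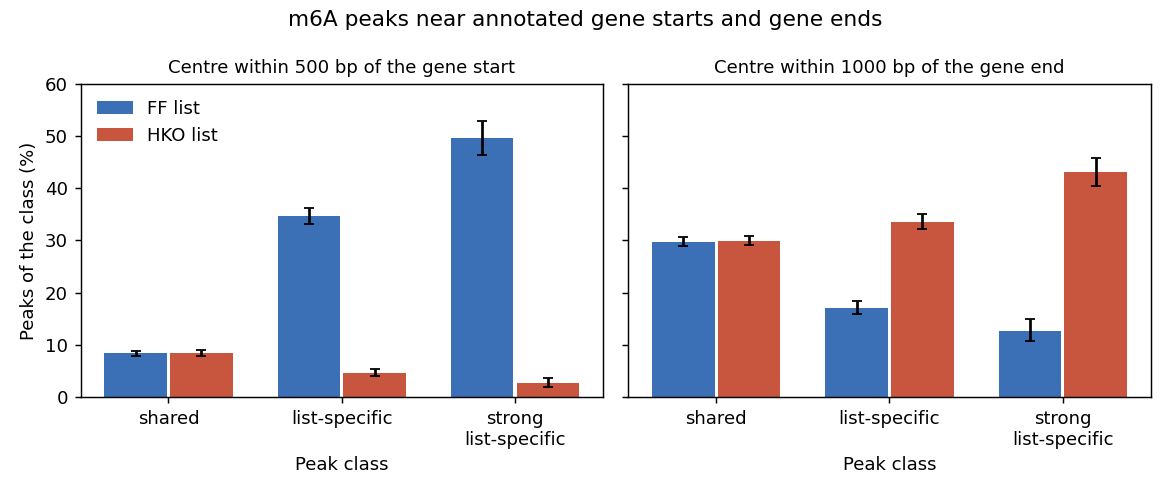
Percent of peaks centred near annotated gene starts and gene ends, for shared, list-specific and strong list-specific peaks of each list, with 95% Wilson intervals that cover counting error only. FF-specific peaks stand at 34.7% near gene starts against 4.71% for HKO-specific peaks; shared peaks, which overlap each other by definition, stand at 8.39% and 8.44%.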

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

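For peak position, the windows, the choice of long genes, the last 10% of the gene, any overlap and the q of 1e-10 were chosen only after the lists were seen. No paired analysis was possible because the labels give no replicate numbers and each genotype had 1 pool. The planned motif shares and regions of the transcript were not run, for want of sequence and transcript models. Depth limits the lists in an unknown way, since they hold no read totals. A q of 1e-05 left 8764 FF and 9621 HKO peaks. It moved the shared part to 81.3% of FF and 74.1% of HKO peaks, and to 89.0% and 85.7% when applied to the counted list alone. The shared part of FF peaks was 76.3% at a q of 0.01. It was 74.0% of FF and 70.1% of HKO peaks at a fold of 2 or more, 60.6% and 58.0% at a reciprocal overlap of 50%, and 73.6% and 73.5% with lists of equal length. Strong list-specific peaks numbered 1800 in FF and 2490 in HKO at a q of 1e-03, 362 and 583 at 1e-10, and 329 and 478 with no peak of the other list in the gene. These follow from the stricter or looser rule itself. Genes in a single list numbered 706 in FF and 1154 in HKO at a q of 1e-05 in both lists, and 327 and 462 when that q was asked of the counted list alone. Numbers of strong peaks and of genes in a single list were higher in HKO in these settings, except that lists of equal length gave 1172 genes in FF and 1141 in HKO. The share of list-specific peaks at gene starts was 38.3% in FF and 3.21% in HKO at a q of 1e-05, 38.5% and 5.53% for any overlap with the window, and 24.1% and 2.75% for a window of 200 bp. It was 30.5% and 3.37% in long genes with peaks in both lists, and 56.5% and 1.91% at a q of 1e-10. The FF share was the higher in each. Of the gene lists, 1 left the middle 95% of random sets at a q of 1e-05 (xenobiotic metabolism, 97.5) and 2 at a fold of 2 or more (cholesterol, 98.3, and bile acid, 98.5). A further 2 did so when peaks were counted in place of genes (erasers, 1.64, and amino acid and urea metabolism, 97.7). The eraser value rests on the 3 FF peaks of Alkbh5 against 1 HKO peak of Fto, and for the other lists the cause was not tested. In all, 25 values of these results stayed within 1.5 times of a count or within the interval of a share, and 35 moved beyond those limits. For single gene lists, 95 of 100 percentiles kept their side of the middle 95% of random sets. No list lay outside that range in the main setting, so a reversal could not be counted. The balance did change sign in some lists, such as insulin signalling (0.0526 as deposited, -0.0125 with peaks counted). Taking the last 10% of the gene span as its end gave 25.6% of FF-specific and 50.9% of HKO-specific peaks.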

Other observations

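The gene families in this part, the test of weak peaks, and the questions of uneven coverage and of paralogs were chosen only after the results were seen. The families were picked because their members had been noticed or for comparison, so their counts describe these lists and are no test of a lean. Grouped by symbol, genes of the mitochondrial respiratory chain and ATP synthase were more often in the FF list alone. Of 55 members with a peak, 21 had a peak in the FF list and none in the HKO list, among them Ndufb7 (fold 3.90), Ndufa2 (2.57), Ndufs6 (7.32), Ndufb8 (6.61), Cox17 (2.70) and Uqcrh (3.32), and 6 had the reverse, among them Cox8a (7.81) and Uqcr10 (1.87). Proteasome genes had 8 of 27 members in the FF list alone, among them Psmb4 (5.30) and Psmc2 (6.79), and 2 in the HKO list alone, Psmc4 and Psmd11.

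Of 50 cytochrome P450 genes with a peak, 21 were in the HKO list alone and 3 in the FF list alone, Cyp4f13, Cyp4f15 and Cyp4f16. Without peaks at gene starts these were 22 and 2 among 44. All 21 genes in the HKO list alone, except Cyp2c38, Cyp39a1 and Cyp3a59, had a peak centred within 1000 bp of the gene end. HKO-specific peaks were frequent there across the whole list (33.6%, against 17.1% of FF-specific peaks). Counts without peaks at gene ends were not made. Cyp2d13 and Cyp2d37-ps, both in the HKO list alone, are transcribed pseudogenes and were counted as members. The other HKO members ranged over drug and steroid metabolism, from Cyp2e1 (fold 12.5) and Cyp2a22 (44.1, uncertain because reads may be shared with related genes) to Cyp26a1 (12.3), which breaks down retinoic acid, and Cyp39a1 (3.69), an oxysterol hydroxylase. The family carried 26 strong list-specific peaks in the HKO list and 2 in the FF list. Solute carriers had 30 of 184 members in the HKO list alone and 9 in the FF list alone (28 and 6 of 174 without peaks at gene starts). Their balance stood at percentile 99.7 of random gene sets with all peaks, and at 90.3 without start peaks. The balance without start peaks, 0.126, lay inside the range of random sets (0.00575 to 0.149), which itself leaned to the HKO list. Ribosomal protein genes had 6 and 4 among 27 (4 and 3 among 23 without start peaks), in the same order. Genes whose symbols start with Zfp, Zkscan or Zscan, many being zinc finger genes, had 20 and 18 among 293 (20 and 17 among 292). These genes were named after their values were seen. Among genes of the Y chromosome, Eif2s3y had 2 peaks in each list, Uty 0 in FF and 2 in HKO, and Kdm5d 0 and 1.

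FF-specific peaks lay near gene starts more often than HKO-specific peaks (34.7% and 4.71%), although most of each class lay elsewhere. Weak peaks near the threshold do not account for this, since at a q of 1e-10 or less 56.5% (51.4 to 61.4) of FF-specific and 1.91% (1.10 to 3.32) of HKO-specific peaks were at starts. Short genes and genes with a peak in a single list do not either. The shares were 30.5% (28.4 to 32.7) and 3.37% (2.70 to 4.19) in genes with peaks in both lists and a span of 10000 bp or more. Peaks were not paired within a gene, so the peaks of the lists may still lie on different genes among these. Uneven coverage of transcript starts or of GC-rich sequence between the libraries cannot be told apart from the genotype: of all peaks, 15.0% of FF and 7.38% of HKO peaks were at starts, and no read counts were used here that would separate them. Both that and a change in methylation after loss of ALKBH5 stay open as hypotheses, as does binding of the antibody to the cap-adjacent nucleotide, which was not tested.

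The absence of Alkbh5 peaks from the HKO list was set against ordinary turnover of peaks. Turnover was rare among genes with as many FF peaks: 11 of 886 (1.24%, 0.695 to 2.21), Alkbh5 itself included, had no HKO peak. These genes were matched on the number of FF peaks and not on peak position. The Alkbh5 peak centred 120 bp from the gene start lay where FF-specific peaks were frequent, so the rate may understate turnover for such genes. A candidate explanation is the loss of Alkbh5 RNA in the knockout, which the peak lists alone cannot test, since they give no RNA level.

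Without peaks within 500 bp of gene starts, respiratory chain and proteasome genes together had 10 members in the FF list alone and 13 in the HKO list alone, at percentile 32.9 of random gene sets, against 29 and 8 with them, so their excess in the FF list may come from the same source as the start peaks. For cytochrome P450 genes, reads shared between near-identical copies were weighed. Of the 12 members that are alone in their subfamily by symbol, 5 were in the HKO list alone and 0 in the FF list alone, which settles nothing further because the family was picked for its HKO members. For the 16 genes in the HKO list alone that have subfamily members, shared reads cannot be told apart from a difference in methylation or RNA level, because no sequence was used to define the copies. A difference between the genotypes remains open for all these families and was not tested.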
